A study of Homo sapiens with 4 samples.

How the data were processed

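Gene expression was measured on 4 two-colour cDNA arrays of A549 cells, each with a let-7a-3 overexpressing culture in 1 channel and a parental culture in the other. Per the labels, the numbered RNA sources of the channels change places between arrays 1 and 3 and arrays 2 and 4. The labels number the sources of each channel differently on every array and call the arrays replicates, and the series text speaks of biological replicates. Which source numbers are the let-7a-3 cultures is not given in the sources used here. That the 2 number series are the 2 conditions is a reading of the stated dye swap.

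Per the series design text, the authors processed the scanner files with ArrayMagic, including variance-stabilizing normalization (VSN), and analysed them with limma. The deposited values are log ratios, with 1 column per array and no missing values. Their base (log2 or natural log), the channel in the numerator, and whether the arrays had been turned to 1 orientation before deposit are not stated. Software versions, spot filters and the averaging of spots are not given in the sources used here, and the table holds no intensities, so no filter on dim probes was possible. The columns of arrays 1 and 3 are usually written with 9 significant digits and those of arrays 2 and 4 with 6, so the 2 orientations were written out differently. VSN compresses ratios of dim spots, so that small log ratios can stand for larger changes there. The control was the parental line, so effects of transfection and selection are not separated from those of let-7a-3.

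The deposited log ratios were used with no further normalization. Probes were named through the platform annotation, and 20963 of the 20976 probes with 1 symbol had a gene ID in the GRCh38.p14 gene table, which changed 0 symbols. Probes with several symbols or none entered the probe-level tests and were not named. For gene-level values all probes of a symbol were averaged. Each probe and each gene was fitted in limma 3.58.1 (R 4.3.3) with 2 coefficients, 1 common to all arrays (the shared component) and 1 that follows the dye orientation (the alternating component). This leaves 2 residual degrees of freedom, to which empirical Bayes moderation added 7.22 at the probe level. Tests were two-sided with Benjamini-Hochberg adjustment over all probes or all genes, at a threshold of 0.05. The ± values are standard deviations over the 4 arrays and therefore hold the other component too.

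Before the data were examined, the tests, the alternatives, 23 gene lists, the rule for named genes and the rule for orientation were fixed. By the orientation rule the alternating component was the condition effect if the mean Pearson correlation of the 4 pairs of opposite orientation lay below 0. It was -0.059, and the rule was set aside for the order of the text after the clone agreement had been seen. Clone agreement was measured per gene, as the sign of the called probe with the smallest p against the sign of the mean of the gene's other probes. Its definition was settled after a first look at pairs of probes.

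Named genes are the 12 probes with the largest positive and the 12 with the largest negative mean among probes with 1 symbol past the threshold and with 1 sign on all 4 arrays, 1 probe per gene, in each component. Up to 4 members per gene list with the largest moderated statistic follow, and then genes named in any case where measured, such as HMGA2 and MYC. Gene lists were tested with camera (preset correlation of 0.01), with camera and an estimated correlation, and with fry, adjusted over the 23 lists.

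The fit was tested on simulated data with the real spread of 26629 probes and the real alternating component. Of 67 probes changed by 0.25 in the shared component 59.7% were recovered, and of those changed by 0.5 and by 1 all were recovered (67 and 66), with 9 false calls (4.9% of the calls). A list shifted by 0.15 was found among 23, with 0 of the others. The simulated noise was independent between probes and had the moderated variances of the fit. The check therefore does not cover correlation between genes, on which the list tests depend. Alternatives were the fit without the dye term, median centring, scaling to 1 median absolute deviation (MAD), quantile normalization, robust moderation (statmod 1.5.0), no moderation and array weights. Thresholds of 0.01 and 0.1, a minimum size of 0.5, the probe with the largest statistic per gene, probes with 1 symbol, the other component, and leaving out each array were also tried. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.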

Results

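RNA from A549 cells, a human lung adenocarcinoma line, was compared on 4 two-colour cDNA arrays between cultures overexpressing let-7a-3, a gene of the let-7 microRNA family, and parental cultures. Each array held 1 let-7a-3 culture and 1 parental culture, and the 4 arrays are numbered here as replicates 1 to 4. The dyes were exchanged between arrays, so that arrays 1 and 3 carried 1 dye orientation and arrays 2 and 4 the other. Every array gave a log ratio for 26629 probes, of which 20976 had 1 gene symbol, 848 had several and 4805 were unnamed here. The symbols covered 12483 genes, 5075 of them with 2 or more probes. The array medians were 0.0062, 0.0174, -0.0022 and 0.0111, and the standard deviations lay between 0.173 and 0.193. The base of the logarithm and the channel in the numerator are not given in the sources used here, so values are log ratios as deposited and no fold is given. The array names mention let-7a-3 overexpression but not the numerator, so which culture a positive value stands for is not known. With the sign turned, every value called positive here would be negative. The small number of arrays limits the precision. The array names do not say whether the let-7a-3 cultures came from 1 transfected line or several. If from 1, the SD and p-values would not cover differences between lines.

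The log ratios of the 4 arrays held a component with the same sign on all arrays (the shared component) and a component that changed sign with the dye orientation (the alternating component). Across probes, which are not independent replicates, arrays of the same orientation correlated with Pearson r = 0.43 (arrays 1 and 3; Spearman rho = 0.33) and 0.56 (arrays 2 and 4; rho = 0.54). For the pairs of opposite orientation r was 0.055 (arrays 1 and 2; rho = -0.031), 0.028 (arrays 1 and 4; rho = -0.083), -0.16 (arrays 2 and 3; rho = -0.30) and -0.16 (arrays 3 and 4; rho = -0.31). The rule set before the data were examined took the alternating component as the let-7a-3 effect when the mean of these 4 Pearson values was below 0. The mean was -0.059, and without array 3 it was 0.042, so in Pearson's r the rule pointed to the alternating component by a margin that 1 array decides. The mean Spearman rho of the same pairs was -0.18, and the pairs left without array 3 were still negative in rho, so by ranks the sign did not depend on that array. The sign of such a mean shows which component varies more across probes. It cannot tell a let-7a-3 effect from a dye effect, so the rule cannot settle which component is the condition. Against the rule, and after the data were seen, the shared component is described first, because the other clones of a called gene carried its sign more often in it, although they lay close to 0 in both. A dye effect that the clones of a gene have in common would also make them agree, which was not tested. Clone agreement therefore cannot mark the shared component as the let-7a-3 effect. Among genes called at a log ratio under 0.5 in size, the mean of the other clones had the sign of the called clone in 119 of 189 genes in the shared component (63.0%, Clopper-Pearson 95% interval 55.7% to 69.9%), and the other clones had a median of 0.028 in the called direction. In the alternating component this held for 296 of 575 genes (51.5%, interval 47.3% to 55.6%; Fisher's exact test of the difference, two-sided p = 0.007), with a median of 0.004. Over called genes of all sizes it held for 160 of 244 genes in the shared component (65.6%) and 302 of 588 in the alternating one (51.4%). Of these, 55 and 13 were called at a size of 0.5 or more, so the sizes compared differ there. The intervals and Fisher's test take genes as independent, although all signs come from the same 4 arrays. They therefore do not measure the spread between arrays or cultures. Both components are reported, and neither reading is settled by the labels.

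**Figure D1:**
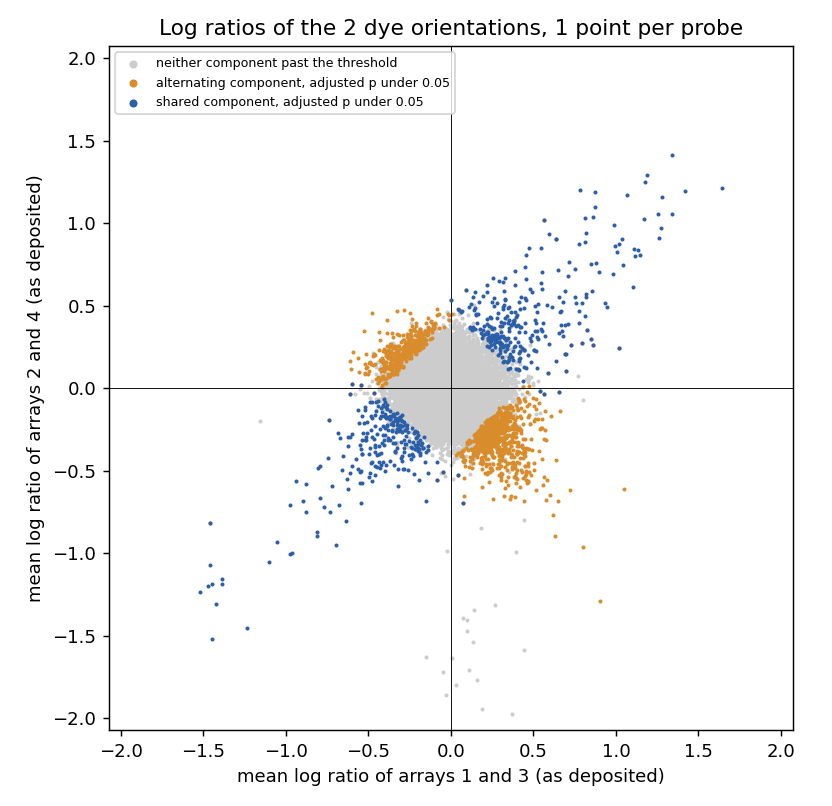
Mean log ratio of arrays 1 and 3 (horizontal axis) against that of arrays 2 and 4 (vertical axis), as deposited, with 1 point per probe. Probes past the threshold in the shared component (550, blue) lie along the rising diagonal with means from -1.49 to 1.43, and those of the alternating component (1141, orange, the 26 past in both drawn blue) lie along the falling diagonal, most of them closer to the origin.

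The first comparison asks which RNAs differed between let-7a-3 and parental A549 cultures, read from the shared component. The largest positive log ratio among the named probes was that of MAGEA6, a cancer-testis antigen (1.43 ± 0.26, SD, n = 4; adjusted p = 5.22e-06). It was followed by DKK1, a secreted inhibitor of Wnt signalling (1.38 ± 0.14), and ERRFI1, a feedback inhibitor of the EGF receptor (1.31 ± 0.20). ATP1B3, a subunit of the sodium pump, stood at 1.24 ± 0.13 and THSD4 at 1.22 ± 0.16. NDRG1, a gene induced by hypoxia, stood at 1.21 ± 0.13, and XBP1, a transcription factor of the unfolded protein response, at 1.12 ± 0.20. The proteoglycan VCAN (1.12 ± 0.22), the receptor NOTCH3 (1.10 ± 0.09), GPR146 (1.08 ± 0.21), the fibrinogen gamma chain FGG (1.03 ± 0.26) and EPM2A-DT (0.99 ± 0.26) completed the 12 named on this side.

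On the negative side, LBH (-1.38 ± 0.20, SD, n = 4, limma adjusted p = 5.43e-06) and the collagen chains COL11A1 (-1.37 ± 0.19) and COL4A6 (-1.33 ± 0.22) had the lowest values among the named probes, together with fibronectin, FN1 (-1.35 ± 0.48). COTL1, an actin-binding protein, stood at -1.32 ± 0.17, the kinase PLK2 at -1.27 ± 0.14 and MFGE8 at -1.27 ± 0.23. CD70, a ligand of the TNF family, stood at -1.14 ± 0.40 and PMEPA1, a gene induced by TGF-beta, at -1.08 ± 0.07. MORC4 (-0.99 ± 0.11), the phosphatase PTPRF (-0.84 ± 0.16) and the aldo-keto reductase AKR1B10 (-0.84 ± 0.04) completed the 12. All 24 had the same sign on 4 of 4 arrays, as the rule for naming them required, and adjusted p between 5.22e-06 and 0.000959 in limma.

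**Figure D2:**
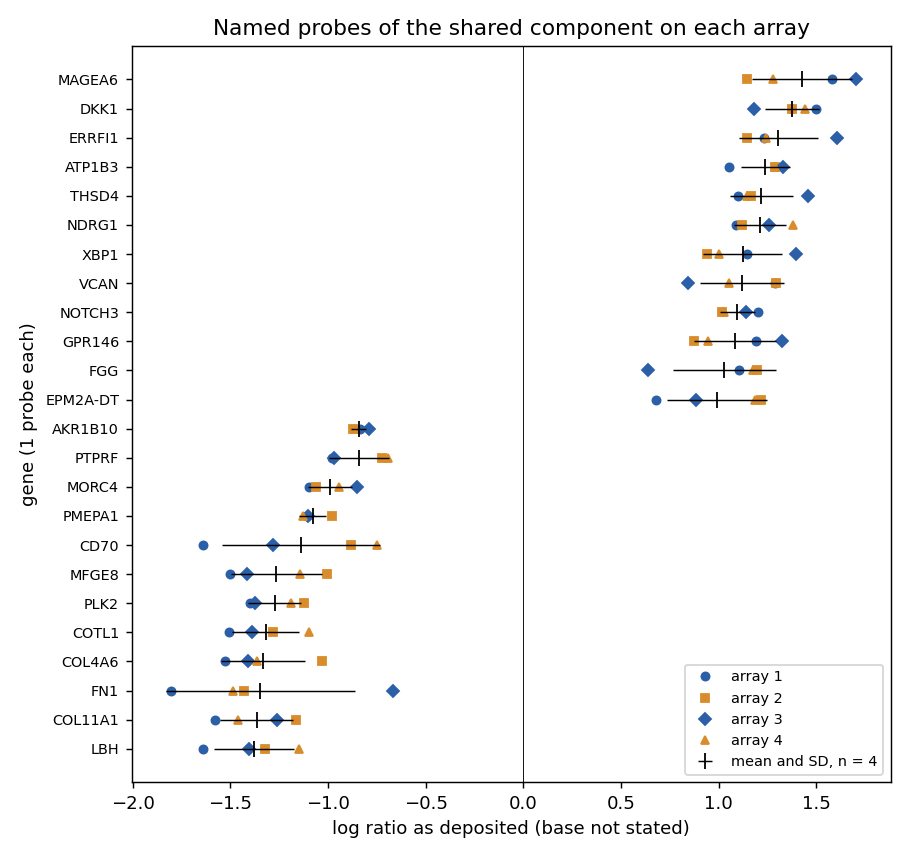
Log ratio as deposited (horizontal axis, base of the logarithm not stated) of the 24 named probes of the shared component on arrays 1 to 4 (symbols), with the mean and SD (black bars, n = 4). Values run from LBH, with a mean of -1.38, to MAGEA6, with a mean of 1.43, and every probe lies on 1 side of 0 on all arrays.

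In the shared component 550 of 26629 probes passed an adjusted p of 0.05 in limma, 298 with positive and 252 with negative log ratios, and 131 of them had a size of at least 0.5. With probes averaged per gene, 379 of 12483 genes passed, 203 positive and 176 negative. The count of probes was 271 without array 2, 286 without array 4, 884 without array 3 and 231 without the dye term, and that of genes was 179, 203, 1471 and 156, and 798 without array 1. Without shared variance between probes, on 2 residual degrees of freedom, 0 probes passed and 2514 had an unadjusted p under 0.05.

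Clones of the same gene often differed. Of the 24 named genes 12 had further probes, and in 4 of them (ATP1B3, VCAN, COL4A6 and COTL1) another probe passed with the same sign, at 1.15 for ATP1B3, 0.97 for VCAN and -1.29 for COL4A6. In NDRG1, GPR146, COL11A1, FN1 and MFGE8 at least 1 other probe had the opposite sign, none of them past the threshold. The other COL11A1 probe was at 0.04, the other MFGE8 probe at 0.04 and the other NDRG1 probe at 0.00. The 4 other GPR146 probes lay between -0.15 and 0.02, and GPR146 averaged over its 5 probes did not pass (0.18, adjusted p = 0.0713). The 3 other FN1 probes lay at -0.21, -0.12 and 0.12, and the mean of all 4 was -0.39. The further probes of ERRFI1 (0.09), THSD4 (0.04) and PTPRF (-0.08) had the sign of the named probe and did not pass.

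**Figure D3:**
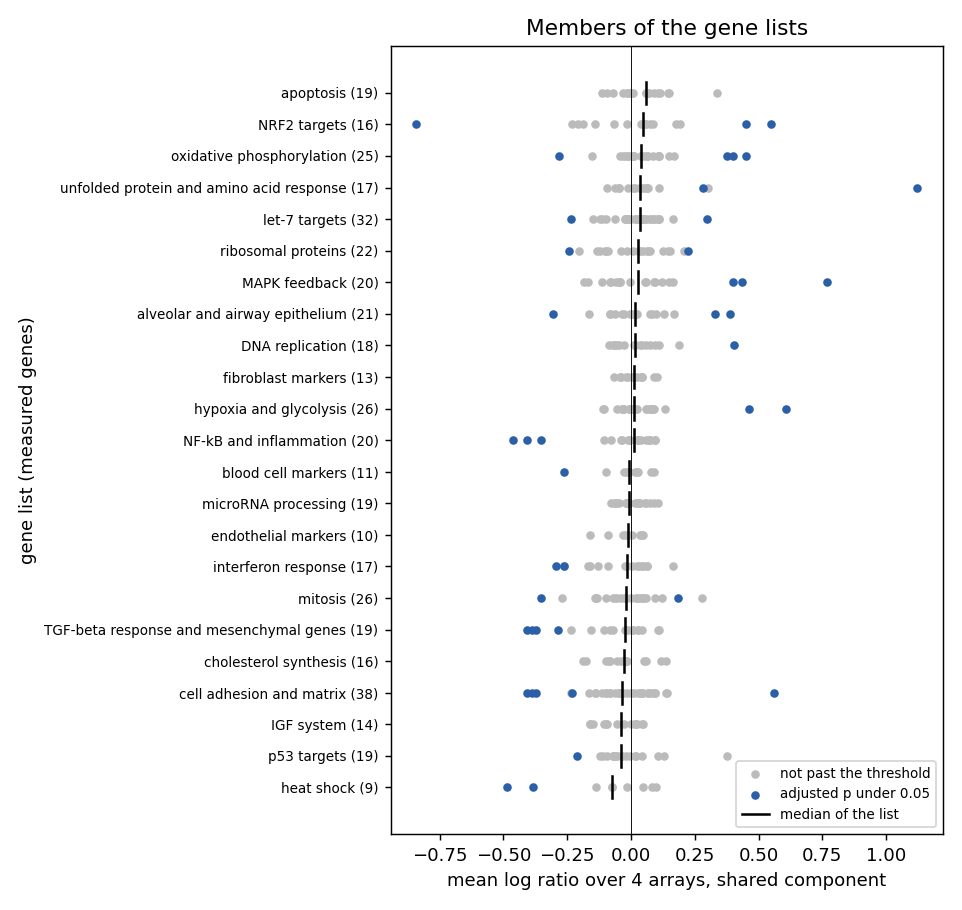
Mean log ratio over 4 arrays in the shared component (horizontal axis) of the measured members of each gene list (vertical axis, number of measured genes in brackets), with the list median as a black bar and members past the threshold in blue. Medians lie between -0.075 for heat shock genes and 0.058 for apoptosis genes.

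The second comparison concerns gene groups, starting with let-7 targets, the group the overexpressed microRNA names. Of 40 listed let-7 targets 32 were measured. EDN1, which encodes endothelin 1, had a positive log ratio (0.30 ± 0.05, SD, n = 4; adjusted p = 0.00734) and the transcription factor PLAGL2 a negative one (-0.24 ± 0.13; adjusted p = 0.0319), and 30 did not pass. Adjusted over the list alone, 2 were positive and 1 negative. At an unadjusted p under 0.05 in limma there were 8 of the 32, against 1822 of all 12483 genes. As a group the targets had a median of 0.035, with 20 positive and 12 negative members, and did not stand apart from other genes in either direction (camera adjusted p = 0.474; adjusted p = 0.684 with an estimated correlation). E2F5 (0.16, adjusted p = 0.0807) and SLC20A1 (-0.12, adjusted p = 0.226) came next. HMGA2, a chromatin protein and textbook let-7 target, was at 0.085 ± 0.14 (adjusted p = 0.542) and MYC at -0.11 ± 0.14 (adjusted p = 0.333). CDK6 was at 0.040 ± 0.080, CDC25A at -0.024 ± 0.23 and DICER1 at 0.059 ± 0.050, none past the threshold. Of the 11 genes to be named in any case, these 5 were measured under their symbols.

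TGF-beta response and mesenchymal genes were the group of the 23 that passed in the shared component, with negative values (camera adjusted p = 0.0109), and the call was lost with an estimated correlation (adjusted p = 0.553). N-cadherin, CDH2 (-0.37 ± 0.05, SD, n = 4; adjusted p = 0.00183), FN1 (-0.39 ± 0.11), vimentin, VIM (-0.41 ± 0.16), and the ligand TGFB2 (-0.29 ± 0.11) passed with negative log ratios, none passed with a positive one, and 15 of 19 measured did not pass. Adjusted over the list alone 5 passed, all negative. The list's call was also lost in fry (adjusted p = 0.110) and without array 4 (adjusted p = 0.0509). The list median was -0.024 and the mean -0.096. The cell adhesion and matrix list, which shares 4 measured genes with it, had 1 positive and 4 negative members past the threshold among 38 (camera adjusted p = 0.0922). LAMB3, a laminin chain, was the positive one (0.56 ± 0.35), and CDH2, FN1 and VIM were among the negative ones.

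Among epithelial genes of the airway and alveolus, the transcription factor FOXA1 (0.33 ± 0.12, SD, n = 4) and keratin 8, KRT8 (0.39 ± 0.13), passed with positive values and HOPX (-0.31 ± 0.08) with a negative one, 18 of 21 did not pass, and the list did not differ from other genes (camera adjusted p = 0.573). In the shared component none of 13 fibroblast markers and none of 10 endothelial markers passed in limma. At an unadjusted p under 0.05 were 1 of 13 (COL1A2, 0.10) and 1 of 10 (TEK, -0.16), against 1822 of all 12483 genes. TEK passed when adjusted over the list alone. Of 11 blood cell markers NKG7 passed (-0.26). The camera adjusted p of these 3 lists was 0.709, 0.474 and 0.573.

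In the unfolded protein and amino acid response XBP1 (1.12) and the chaperone HSP90B1 (0.28) passed and 15 of 17 did not, among them ATF4 (0.30, adjusted p = 0.0517). The camera adjusted p was 0.0922, and 0.711 with the list's estimated correlation of 0.353. Of 9 heat shock genes HSP90AA1 (-0.49 ± 0.23, SD, n = 4) and DNAJA1 (-0.39 ± 0.24) passed, both negative (camera adjusted p = 0.0922). Of 16 NRF2 targets PRDX1 (0.55) and PGD (0.45) were positive and AKR1B10 (-0.84) negative, with a median of 0.048 and a mean of -0.001 (adjusted p = 0.726). PHLDA3 (-0.21) alone passed among 19 p53 targets (camera adjusted p = 0.228). None of 19 apoptosis genes passed in limma, with 6 at an unadjusted p under 0.05, against 1822 of all 12483 genes. CASP9 had the largest moderated statistic (0.34, adjusted p = 0.0788; list adjusted p = 0.221).

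Of 20 MAPK feedback genes IER3 (0.77 ± 0.17, SD, n = 4), ETV4 (0.43 ± 0.16) and DUSP5 (0.40 ± 0.35) passed, all positive, and FOS was at -0.17 (adjusted p = 0.0844; list adjusted p = 0.221). Of 20 NF-kB and inflammation genes the chemokines CXCL1 (-0.46 ± 0.10), CXCL3 (-0.41 ± 0.13) and CXCL5 (-0.35 ± 0.10) passed, all negative, while the list median was 0.011 and its mean -0.046 (list adjusted p = 0.356). PSMB8 (-0.29), an immunoproteasome subunit, and HLA-B (-0.26) passed among 17 interferon response genes, both negative, and 5 passed adjusted over the list alone (list adjusted p = 0.0922).

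PCNA (0.40 ± 0.13, SD, n = 4) alone passed among 18 DNA replication genes (list adjusted p = 0.510). Among 26 mitosis genes AURKB (-0.35) passed with a negative and CENPF (0.19) with a positive value (list adjusted p = 0.510). In hypoxia and glycolysis NDRG1 (0.61 over its 2 probes) and LDHA (0.46) passed of 26 (camera adjusted p = 0.221), and fry, which asks whether members move 1 way without comparing them with other genes, gave adjusted p = 0.0162. Of 25 oxidative phosphorylation genes SDHA (0.45), COX7C (0.40) and NDUFB5 (0.38) were positive and NDUFA8 (-0.28) negative (camera adjusted p = 0.0846). RPL27 (-0.24) and RPS20 (0.22) passed among 22 ribosomal proteins (adjusted p = 0.964). No member passed in limma among 16 cholesterol synthesis genes (adjusted p = 0.221), 14 genes of the IGF system (adjusted p = 0.0945) and 19 microRNA processing genes (adjusted p = 0.964). In these 3 lists ACLY (-0.18), IGFBP6 (-0.16) and AGO2 (0.10) had the largest moderated statistics. An unadjusted p under 0.05 in limma was reached by 3, 6 and 1 members, against 1822 of all 12483 genes. With an estimated correlation 0 of the 23 lists passed, the smallest adjusted p being 0.553. On 2 residual degrees of freedom hardly any list could pass, so this does not show that correlation between genes removes the calls.

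The third comparison is the alternating component, which the rule set beforehand read as the let-7a-3 effect. Values here are turned so that they carry the sign of arrays 1 and 3. MAOB, a monoamine oxidase, had the largest positive mean (1.10 ± 0.77, SD, n = 4; adjusted p = 0.0321), followed by SNAP29 (0.88 ± 0.43), ZNRD2 (0.83 ± 0.38), PRDM2 (0.76 ± 0.19) and SLC49A3 (0.69 ± 0.13). AUTS2 (0.63), PTPRK (0.57), ABCB1 (0.57), LGR4 (0.57), PKDREJ (0.56), HAND2-AS1 (0.55) and ORMDL3 (0.54) followed. On the negative side NES, which encodes nestin, stood at -0.47 ± 0.18, SLC22A16 at -0.41, SNRK at -0.40, NUDT1 at -0.40, PAPPA2 at -0.39 and EHMT1 at -0.38. HSFY1, VPS35, DSTN, PARK7, PA2G4 and TRAK2 lay between -0.36 and -0.34. In most of these genes with further probes at least 1 other clone went the opposite way, as in SNAP29 (-0.26) and EHMT1 (0.42). Averaged over their probes, MAOB (0.35, limma adjusted p = 0.0552), SNAP29 (0.31, adjusted p = 0.0807), PRDM2 (0.12, adjusted p = 0.149) and EHMT1 (0.001, adjusted p = 0.994) did not pass. Among the named genes with further probes, only HAND2-AS1, SLC22A16 and DSTN passed when averaged.

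In the alternating component 1141 probes passed, 747 positive and 394 negative, but 25 of them reached a size of 0.5, against 131 of 550 in the shared component. The components had 26 called probes in common, where independent lists of these lengths would share 23.6. At the gene level 411 genes passed, 237 positive and 174 negative. The count of probes was 113 without array 2, 138 without array 4, 1874 without array 1 and 102 without the dye term, and that of genes was 39, 69, 2292 and 10, and 1580 without array 3. Without shared variance between probes 4 probes passed, and 4122 had an unadjusted p under 0.05. None of 32 let-7 targets passed in this component in limma (camera adjusted p = 0.870), THBS1 (-0.18, adjusted p = 0.0587) having the largest moderated statistic. At an unadjusted p under 0.05 in limma there were 4 of the 32, against 3197 of all 12483 genes. Oxidative phosphorylation genes were the list that passed, with a median of -0.087 (camera adjusted p = 0.00669), and NDUFB9 (-0.20, adjusted p = 0.0473) was the member past the threshold. This was lost in camera with an estimated correlation (adjusted p = 0.921), in fry (adjusted p = 0.0984) and without array 4. The list's estimated correlation, 0.004, lay below the preset 0.01. The 2 residual degrees of freedom of that setting, and not correlation between genes, therefore removed the call there.

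In the alternating component the endothelial markers ESAM (-0.31 ± 0.11, SD, n = 4; adjusted p = 0.0236) and TEK (-0.20 ± 0.19; adjusted p = 0.0439) passed, both negative, of 10 measured (list adjusted p = 0.870). Of the MAPK feedback genes SPRY2 (0.30 ± 0.16) and DUSP5 (0.29 ± 0.47) passed, both positive, and of the adhesion and matrix genes LAMB3 (0.30 ± 0.65). The death receptor TNFRSF10A (-0.24) and BBC3 (0.23), which is also in the p53 list, passed among apoptosis genes. RPL6 (-0.25), RPL10 (-0.21) and RPS19 (-0.20) passed among ribosomal proteins, all negative. IL11 (-0.22) passed in the inflammation list, LDHA (-0.21) in hypoxia and glycolysis, and GEMIN4 (-0.20) in microRNA processing. DUSP5, LAMB3 and LDHA had passed in the shared component as well. The other 13 lists had no member past the threshold in limma. Between 1 and 10 of their members had an unadjusted p under 0.05, against 3197 of all 12483 genes. Apart from oxidative phosphorylation no list passed in camera, the smallest adjusted p being 0.474 for blood cell markers.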

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

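The tests of clone agreement, of variance by source plate and of plate medians with all probes kept in the fit were chosen after the values had been seen, and the recount on plates of at least 10 clones alone was fixed before its result.

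In 8 of 138 named results (5.8%, where chance gives about 5%) 1 array stood apart from the other 3. For ATP1B3 array 1 was at 1.052, with the others between 1.29 and 1.33. FGG was at 0.64 on array 3 and between 1.11 and 1.20 elsewhere. In the alternating component, turned, ZNRD2 was at 0.27 on array 2, with the others between 0.95 and 1.07, and EHMT1 at -0.652 on array 4, with the others between -0.31 and -0.26. At the gene level in the shared component MKI67, which did not pass, was at 0.636 on array 1 and between 0.12 and 0.20 elsewhere. RPS16 was at 0.07 on array 1 and between 0.24 and 0.26 elsewhere. CDK6 was at -0.079 on array 3 and between 0.071 and 0.094 elsewhere, and DICER1 at -0.016 on array 2 and between 0.080 and 0.087 elsewhere.

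The alternating component held more called probes (1141) than the shared one (550). Among genes called at a size under 0.5 in the alternating component, the other clones followed the sign in 51.5% of 575 genes, with an interval over genes that holds 50%. In the shared component they did so in 63.0% of 189 genes. The bounds of the intervals nearly meet (55.6% and 55.7%), and the other clones lay close to 0 in both (medians in the called direction of 0.004 and 0.028). The outcome written down, after the values were seen, against the alternating calls as the let-7a-3 effect was met, but it cannot decide. A dye effect common to the clones of a gene would raise agreement, and plate effects could lower it. Source plate explained 4.41% of the variance of the alternating component over 21063 probes, above the highest of 100 shuffles (1.01%), and -1.17% in the shared component. Plates may therefore contribute to the alternating component. Taking each plate's median off on plates with at least 10 clones (14334 probes), with all probes kept in the fit, left 767 called probes against 470, and on those plates 365 against 285, from 596 against 346; in a fit of those plates alone the alternating calls fell from 368 to 62 while 75.4% of the shared count was left (242), which met the outcome set beforehand for plates as the cause. On those plates alone, however, the alternating component began with only 1.15 times as many calls, so the recounts leave open whether plates account for the whole excess, and how the table was turned stays open too: with balanced orientations, gene-specific dye effects fall in the alternating component if it was turned and in the shared one if it was not.

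The 8 ways of giving signs to 4 arrays are too few for a share under 0.05. As many probes as in the shared component (550) came from 2 of the 8, with 1141 as the highest other, and as many as in the alternating component (1141) from 1, with 550 as the highest other. For genes these were 2 (379, highest other 411) and 1 (411, highest other 379). The 6 patterns that match neither component gave 0 probes and 0 genes. In those fits the shared and alternating signals fall wholly or partly into the residual, so low counts were built in and back neither component.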

How the results depend on the processing

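The other component for genes, probes with 1 symbol in the shared component, and all alternatives for the correlation between arrays were chosen after seeing the data. Counts are compared within 1.5 times. Median centring, MAD scaling, quantile normalization, robust moderation and array weights kept all 4 counts of probes and genes within that range. The dye term, moderation, thresholds and left-out arrays did not. The residual with 1 array left out came only from the 2 arrays of the other orientation. Without array 2 or 4 these were arrays 1 and 3 (Pearson r = 0.43), and without array 1 or 3 arrays 2 and 4 (r = 0.56). A lower count without an array therefore does not show that the calls rest on it. Where construction (fewer arrays, another threshold) does not show it, the cause was not tested.

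For the alternating component, the condition effect by the rule set beforehand, 1141 probes passed. There were 102 without the dye term, 4 without moderation, 24 at 0.01, 3154 at 0.1, 25 at a size of 0.5 and between 113 (without array 2) and 1874 (without array 1) with 1 array left out, 138 without array 4. The other component gave 550. For the shared component (550 probes) these were 231, 0 (2514 at an unadjusted p under 0.05), 248, 867, 131 and between 271 (without array 2) and 884 (without array 3), 286 without array 4. Of the 411 genes of the alternating component there were 10, 1, 7, 1400 and 5 under the same settings, between 39 (without array 2) and 2292 (without array 1) with 1 array left out, 69 without array 4 and 1580 without array 3, and 1949 with the probe of largest statistic. Of the 379 genes of the shared component there were 156, 0 (1337 at an unadjusted p under 0.05), 162, 613 and 66, between 179 (without array 2) and 1471 (without array 3), 798 without array 1 and 203 without array 4, and 690 with the probe of largest statistic, a choice that favours large statistics.

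The TGF-beta and mesenchymal list (shared, adjusted p = 0.0109) went to 0.553 with an estimated correlation and 0.11 in fry, and lay between 0.00133 and 0.0509 (without array 4) with 1 array left out. Oxidative phosphorylation (alternating, 0.00669) went to 0.921 and 0.0984, and lay between 0.00295 and 0.0784 (without array 4). The number of lists past the threshold, 1 in each component, was 0 in both with an estimated correlation and 0 in fry in the alternating component. With an estimated correlation, 2 residual degrees of freedom left hardly any list able to pass. In the shared component fry gave 1, hypoxia and glycolysis, and quantile normalization and the probe of largest statistic gave 2, with oxidative phosphorylation added. With 1 array left out it lay between 0 (without array 4) and 5 (without array 1), 3 without array 2, in the shared component and between 0 (without array 4) and 1 in the alternating one. Let-7 targets kept their side of the threshold and their direction in both components under every alternative run (adjusted p between 0.217 and 0.945).

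The mean correlation of arrays of opposite orientation (-0.0585) was 0.0417 without array 3 and -0.159 without array 1. All 24 named probes of the shared component passed under each of the 14 alternatives run for them except no moderation, where 24 were lost. Picked for their size (all beyond 0.5, limma adjusted p at most 0.000959), they passed the settings of 0.01, 0.1 and 0.5 by construction. Of the 24 of the alternating component 11 were lost without the dye term, 15 at 0.01, 12 at a size of 0.5, 24 without moderation, 1 with robust moderation, 6 without array 2 and 11 without array 4. The losses at 0.01 and 0.5 likewise follow from the values in the main fit. No named gene that passed changed sign. The table holds no signal over background, so its effect on dim probes was not assessed.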

Other observations

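Several gene families appeared among the called genes of the shared component, and were chosen after their values were seen, so that no p is given for them. Apart from the neutrophil chemokines, most of which are in the inflammation list, they lay outside the lists fixed beforehand. Of 8 measured MAGE-A genes, cancer-testis antigens of close sequence, 5 passed with positive log ratios: MAGEA6 (1.43), MAGEA12 (0.65 ± 0.16, SD, n = 4), MAGEA2B (0.53 ± 0.32), MAGEA4 (0.32 ± 0.20) and MAGEA3 (0.23 ± 0.16). MAGEA1 (-0.077), MAGEA8 (0.023) and MAGEA11 (0.070) did not pass. Family members share enough sequence for cross-hybridization on cDNA probes, which was not tested. The fibrinogen chains FGG (1.03 ± 0.26) and FGB (0.85 ± 0.25) and the related FGL1 (0.90 ± 0.24) were all 3 measured members of that group and all passed with positive values. Of 8 metallothioneins MT2A (-0.63 ± 0.25), MT1X (-0.45 ± 0.08) and MT1H (-0.39 ± 0.18) passed with negative values, and MT1E was at 0.18 (adjusted p = 0.119). Of 5 neutrophil chemokines CXCL1, CXCL3 and CXCL5 passed, as described for the inflammation list, while CXCL2 (-0.004) and CXCL6 (-0.045) did not.

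The tests of held-out members and of neighbouring genes were fixed before their results. Among 45 nucleolar and ribosome assembly genes 7 passed, all negative (NOP56, RRS1, TSR1, UTP6, RPP40, NIFK and REXO4, from -0.32 to -0.21). The hypothesis that ribosome assembly genes shift together was tested on the 38 that had not passed: their median was -0.008, with 22 negative and 16 positive (camera adjusted p = 0.187, over the 2 hypotheses of this kind). Among 65 secretory pathway genes 11 passed with positive values, XBP1 and SEC11C (0.49) leading, and SEC61B (-0.35) and TRAM1 (-0.56) with negative ones. The 52 that had not passed had a median of 0.011 (camera adjusted p = 0.311). Neither test passed 0.05 before or after this adjustment. The outcome set beforehand for rejecting the hypotheses was met, but it was set wrongly, since a list without its called members cannot exclude a shift, and both stay open.

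A difference in copy number between the culture series was tried as a hypothesis for the called genes of the shared component. Medians over 485 windows of 25 neighbouring measured genes spread more widely than in any of 1000 shuffles of gene order (SD 0.0178 against a mean of 0.0161; permutation p = 0.001, the smallest they can give). The alternating component gave much the same (permutation p = 0.002), so the test does not separate copy number from other properties that neighbouring genes have in common. The largest window median was 0.056 in size in the shared component, and the alternating one ranged from -0.091 to 0.076. In the shared component no window median reached 0.186, the smallest size of a called gene. A shift of that size over the median of a whole window was therefore not seen. Smaller or shorter copy number differences stay open.

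Single spots stood far off on 1 array. With a size of at least 1.5 on 1 array and under 0.5 on the other 3, there were 14 probes on array 2, all negative, 3 each on arrays 3 and 4 and 0 on array 1. CYP4A22, chosen after its values were seen, was at -3.84 on array 2 and between -0.17 and 0.11 elsewhere. None of these probes passed in limma in either component.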
